A study of Escherichia coli str. K-12 substr. MG1655 with 5 samples.

How the data were processed

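RNA was sequenced from Escherichia coli K-12 MG1655, a standard laboratory strain, and from a strain lacking yfeC. Per the labels, both were grown at 37 °C with agitation in M9 minimal medium with 0.2% (w/v) glucose, started from an overnight culture at an OD600 of 0.05 and kept for 24 h. The extraction protocol in the labels speaks of exponentially growing cells, which differs from a harvest after 24 h, and the growth phase at harvest was therefore left open. Ribosomal RNA was depleted before library construction, per the labels' protocols. Samples were grouped by the genotype in their titles into 3 wild-type and 2 yfeC deletion libraries, and the replicate numbers were taken from the titles.

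The submitters' processing notes name Bowtie 1.1.2 and featureCounts. The genome build, the annotation, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. The deposited values are log2 values: raised back from log2(TPM + 1), they summed to 1000000 in each library, so the authors' unit was taken as log2 of TPM (transcripts per 1000000) plus 1. All 4305 genes of the table (4288 protein-coding genes and 17 pseudogenes) were matched by locus tag to the RefSeq gene table of assembly ASM584v2, which was used for symbols and neighbouring genes. No coordinates are given because the build behind the values is not named. Ribosomal and transfer RNA genes were not analysed here.

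Read numbers were recovered from the TPM values, since TPM multiplied by the gene length of the reference table was a whole multiple of a single step in each library. This held within a tolerance of 0.02 in all libraries for 4287 genes (99.6%). The recovered totals were 728649, 748690 and 765378 reads in wild-type replicates 1 to 3 and 884653 and 829963 reads in deletion replicates 1 and 2. The median gene had 29 to 40 reads, so that genes of low abundance rest on few reads. Counting intervals on ratios of reads are exact 95% intervals and, like the floor of 3 reads over a group at 0, cover counting error alone. Overlapping genes and near-identical copies can share reads, and values of such genes are uncertain. Overlaps are marked below for some of the genes only.

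The 4075 genes with at least 1 TPM in at least 2 libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a term for genotype and an intensity trend in the empirical Bayes step. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was the threshold. Fold changes given as log2 refer to TPM + 1 and understate the change of low genes. The design assumed TPM values, and since the deposited values already were log2(TPM + 1), they entered the fit as they were. Before the data were examined, 48 gene lists, the tests, most of the alternatives and the rule for named genes were fixed. Of the lists, 47 had at least 3 genes tested and were compared with all other genes by camera, a competitive set test in limma, with a preset correlation of 0.01. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives.

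Genes were named by rule: yfeC and the 3 neighbouring genes on each side; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with a mean of at least 10 TPM in the higher group and no overlap between the groups; and, for each list described, up to 4 members past the threshold with the largest change. The neighbouring transfer RNA genes were not analysed here. Other alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 10 TPM, median-ratio scaling, quantile normalization, empirical Bayes without trend or with robust fitting, the replicate number as a block, an absolute log2 fold change of at least 1, and each library left out in turn. A voom fit on the recovered reads and thinning of the reads to the lowest library total were added after the data were seen.

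In simulated counts with the wild-type means and the libraries' depths, 100 genes were changed by 1 log2 unit and 100 by 2, evenly up and down. At a dispersion of 0.005 (4030 genes tested) the fit recovered 62% and 94% of them, and 4.88% of its calls were false. At a dispersion of 0.03 (4026 genes tested) it recovered 26% and 85%, with 5.93% false calls. The simulation held few changed genes and no shift of the median. Its share of false calls therefore does not carry over to the real comparison. Within a group, pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 1.91 to 2.53, so each was counted as a replicate. The labels do not say that replicates came from separate cultures, and p-values measure the spread between these samples, which may be technical. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.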

Results

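Messenger RNA levels of 4305 genes were compared between 3 wild-type libraries and 2 libraries of a yfeC deletion strain of E. coli K-12 MG1655 in M9 glucose medium. The series treats yfeC as a candidate transcription factor, and the comparison asks which transcripts differ when it is absent. The libraries held 728649 to 884653 recovered reads. The 10 most abundant genes took 20.17% to 20.99% of the TPM in the wild type and 15.3% to 15.4% in the deletion strain.

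The yfeC transcript was almost absent from the deletion libraries. It stood at 1377, 1283 and 1235 TPM in the wild-type libraries and at 4.59 and 0 TPM in the deletion libraries (log2 fold change -9.10, SE 0.59, adjusted p = 3.9e-05). These values rest on 1623 reads in the wild type and 2 in the deletion strain, a ratio of 545 in depth-corrected reads (95% counting interval 151 to 4508). The yfeC level, as a log2 fold change, was -10.34 without deletion replicate 1 and -7.86 without deletion replicate 2. The adjacent yfeD fell from 556 ± 70.7 TPM (SD, n = 3) to 373 ± 51.5 TPM (SD, n = 2), a log2 fold change of -0.57 (SE 0.13, adjusted p = 0.015). gltX, which encodes glutamyl-tRNA synthetase, was at 65.9 ± 5.46 and 83.0 ± 5.05 TPM (adjusted p = 0.18), and pdeA, which encodes a cyclic-di-GMP phosphodiesterase, at 7.50 ± 2.69 and 11.1 ± 3.67 TPM (adjusted p = 0.48). The call of yfeD was lost without wild-type replicate 1 (adjusted p = 0.051), without deletion replicate 1 (adjusted p = 0.11) and in the fit without an intensity trend.

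**Figure D1:**
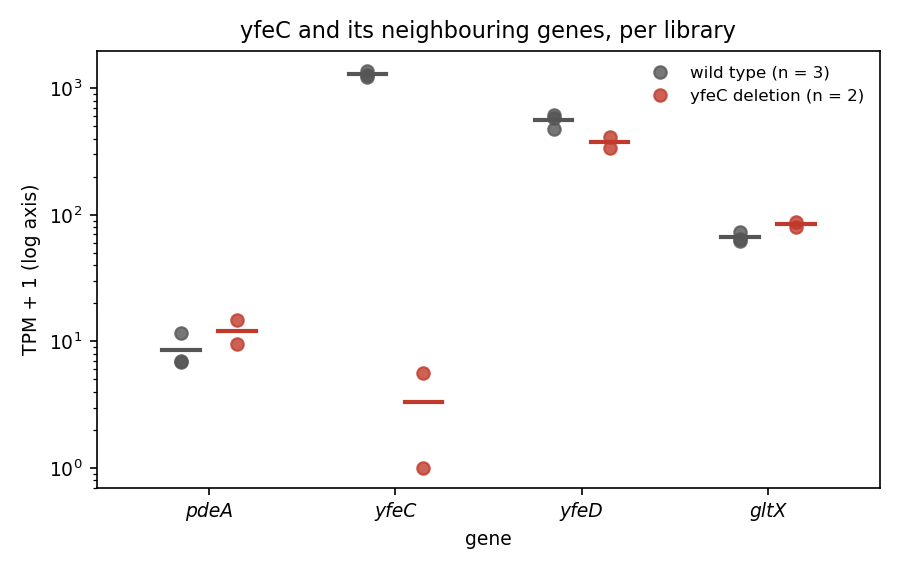
TPM + 1 on a log axis for yfeC and 3 neighbouring genes, with a point per library and a bar at each group's mean (wild type, n = 3; yfeC deletion, n = 2). The yfeC points lie above 1000 in the wild type and below 10 in the deletion strain, where 1 of the 2 libraries is at 0 TPM.

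Between the genotypes, 1054 of the 4075 genes tested (25.9%) passed the threshold, 750 of them higher and 304 lower in the deletion strain. A change of at least 1 log2 unit was reached by 247 of the higher and 96 of the lower genes. The median log2 fold change of all genes tested was 0.27, and median-ratio scaling brought it to 0.03. With that scaling, 340 genes were higher and 478 lower, which moved the share of higher genes among the calls from 71.2% to 41.6%. All 340 genes higher with scaling were also higher without it, all 304 genes lower without scaling were also lower with it, and no gene was called in opposite directions. The scaling divides each library by a single factor and moves nearly all changes by a similar amount. That agreement was therefore largely fixed by construction. Log2 fold changes of single genes are on the deposited scale, and subtracting 0.27 gives the change relative to the median gene. Without deletion replicate 1 the number of higher genes was 352, without deletion replicate 2 it was 391, and without an intensity trend 343 genes were higher and 150 lower.

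**Figure D2:**
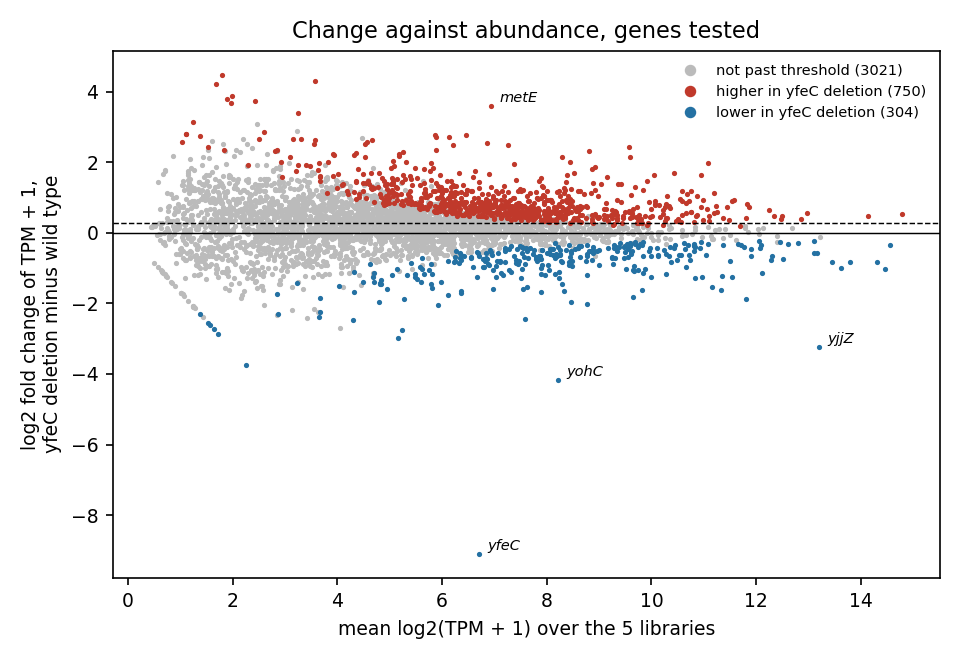
Log2 fold change of TPM + 1 (yfeC deletion minus wild type) against the mean log2(TPM + 1) over the 5 libraries for each gene tested, with 750 higher genes in red, 304 lower genes in blue and the others in grey. The dashed line marks the median of all genes at 0.27, and yfeC lies lowest at -9.10.

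Among abundant transcripts, the largest fall after yfeC was that of yohC, from 955 ± 95.2 to 51.7 ± 4.61 TPM (log2 fold change -4.18, SE 0.11, adjusted p = 1.0e-06). yjjZ, among the most abundant transcripts of the wild type, fell from 23242 ± 323 to 2448 ± 215 TPM (log2 fold change -3.25, SE 0.06, adjusted p = 1.2e-07). ybaQ (log2 fold change -2.97), uxaB (-2.76), tdcB (-2.46), ydcK (-2.44) and entB (-2.04) followed. uxaB encodes tagaturonate reductase and tdcB the catabolic threonine dehydratase. ymgI had 8 reads in the wild type and 0 in the deletion strain, at least 1.79-fold lower against a floor of 3 reads over the group. The calls of yohJ (-2.39), dgcC (-2.30) and fau (-2.24) also passed. yohJ was lost without deletion replicate 2 (adjusted p = 0.061). dgcC was lost without deletion replicate 1 or 2 (adjusted p = 0.0504 and 0.068). fau was lost without wild-type replicate 1, 2 or 3 (adjusted p = 0.077, 0.059 and 0.11) or deletion replicate 1, where its log2 fold change was -1.20 (adjusted p = 0.15). fau was also lost without an intensity trend (adjusted p = 0.099) and with the replicate number as a block (0.059). ymgI was lost in a voom fit on the recovered reads (0.089). ydcK overlaps rimL, and yohJ overlaps yohK, so their values are uncertain.

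Among the 12 genes with the largest rise, metE and gltB rested on 369 and 427 reads in the wild type. metE, which encodes the cobalamin-independent methionine synthase, rose from 45.0 ± 8.02 to 547 ± 6.33 TPM (log2 fold change 3.59, SE 0.16, adjusted p = 7.8e-06). gltB, which encodes the large subunit of glutamate synthase, rose from 26.4 ± 4.99 to 184 ± 2.87 TPM (log2 fold change 2.77, SE 0.21, adjusted p = 7.3e-05). The other 10 rested on few reads. hycA, a regulator of formate hydrogenlyase genes, had 0 reads in the wild type and 26 in the deletion strain, at least 12.9-fold higher, and ydiT had 0 and 8, at least 3.97-fold higher, each against a floor of 3 reads over the group. The read ratio was 37.2 for hycF (95% counting interval 6.09 to 1527), 29.0 for hycD (7.51 to 248), 43.1 for flgD (7.15 to 1762) and 16.4 for yqgG (2.38 to 704). flgB (log2 fold change 4.30), flgC (3.40) and fliS (2.87), genes of the flagellum, completed the group together with thrL, whose 0 and 3 reads, both at or under the floor, allow no fold and whose call was lost in the voom fit (adjusted p = 0.33) and which was not tested on thinned reads. Without a single library, 8 of the 12 lost their call. hycA, thrL and ydiT, at 0 in the wild type, were not tested without either deletion library. flgB was lost without deletion replicate 1 (adjusted p = 0.054). hycF and flgD were lost without deletion replicate 2 (0.060 and 0.069). hycD and flgC were lost without deletion replicate 1 (0.083 and 0.13) or 2 (0.056 and 0.096), and ydiT without wild-type replicate 1, 2 or 3 (0.066, 0.058 and 0.063). yqgG was lost without wild-type replicate 2 or 3 or deletion replicate 2 (0.069, 0.099 and 0.25) and fliS without wild-type replicate 1 or 2 or deletion replicate 1 or 2 (0.053, 0.064, 0.22 and 0.11). yqgG and fliS were also lost with median-ratio scaling (adjusted p = 0.051 and 0.065). flgB, flgC, fliS and yqgG were lost with a pseudocount of 0.1 (0.056, 0.11, 0.12 and 0.069) and, like ydiT (0.062), without an intensity trend (0.062, 0.098, 0.10 and 0.11). With quantile normalization yqgG, fliS and ydiT were lost (0.058, 0.067 and 0.051), and ydiT and yqgG with the replicate number as a block (0.059 and 0.098) and in the voom fit (0.11 and 0.10). yqgG was also lost on thinned reads (0.062). Its log2 fold change of 3.74 became 2.65 without deletion replicate 2, and that of fliS became 2.14 without wild-type replicate 1. hycF, yqgG, ydiT and fliS overlap other genes, so their values are uncertain.

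Of the 47 gene lists tested, 20 passed the threshold of the set test, 15 upward and 5 downward. None of the 20 passed with an estimated correlation between genes, and that p stands beside each list. That correlation was estimated from 3 residual degrees of freedom and is itself uncertain. Some lists hold runs of neighbouring genes that moved together, such as hisD to hisI and fdx to iscR (7 genes each). Their member counts are therefore not independent.

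Stress and stationary-phase genes under the sigma factor RpoS were lower in the deletion strain. Of 23 members, 17 fell, 6 did not pass and none rose, with 19 lower adjusted over the list alone and 22 with median-ratio scaling (set test adjusted p = 2.0e-12, and adjusted p = 0.09 with an estimated correlation). yjbJ fell from 768 ± 63.4 to 189 ± 20.8 TPM (log2 fold change -2.02, SE 0.11), and sodC, which encodes periplasmic superoxide dismutase, from 612 ± 61.7 to 157 ± 20.9 TPM (-1.96, SE 0.12). osmB (-1.13, SE 0.09) and aldB, an aldehyde dehydrogenase gene (-0.90, SE 0.08), followed. Of 14 acid resistance genes, 9 fell and none rose, with 10 lower both adjusted over the list alone and with median-ratio scaling (set test adjusted p = 2.2e-08, and adjusted p = 0.09 with an estimated correlation). gadE, the central activator of that system, fell from 511 ± 36.3 to 162 ± 8.24 TPM (-1.65, SE 0.10). The glutamate decarboxylase genes gadA (-1.099) and gadB (-0.94) fell too, but they are nearly identical copies and their separate values are uncertain. The call of mdtF (-1.14) was lost without deletion replicate 1 or 2 (adjusted p = 0.096 and 0.064).

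Genes of iron uptake were lower in part, and those of iron-sulfur cluster assembly higher. Of 35 iron acquisition genes, 13 fell and none rose, against 14 lower and 1 higher adjusted over the list alone and 16 lower with median-ratio scaling (set test adjusted p = 3.5e-10, and adjusted p = 0.09 with an estimated correlation). The enterobactin synthesis genes entB (-2.04, SE 0.17), entA (-1.75, SE 0.18) and entC (-1.64, SE 0.16) fell, and bfd, which encodes bacterioferritin-associated ferredoxin, fell from 4014 ± 259 to 1321 ± 151 TPM (-1.61, SE 0.09). Of 8 ISC genes, 7 rose, against 8 adjusted over the list alone and 5 with median-ratio scaling (set test adjusted p = 0.0016, and adjusted p = 0.29 with an estimated correlation). iscS rose from 584 ± 28.7 to 1223 ± 138 TPM (1.06, SE 0.09), and iscU rose too (1.04, SE 0.07). Of 10 zinc and manganese uptake genes tested, 3 fell and none rose, with 4 lower adjusted over the list alone and 3 with median-ratio scaling (set test adjusted p = 0.00094, and adjusted p = 0.15 with an estimated correlation). They were mntS (-1.02), the manganese importer gene mntH (-0.97) and znuA (-0.46). entA and entB overlap, as do mntH and ypeD, and mntS overlaps rybA. The call of znuA was lost without wild-type replicate 1 or 2 or deletion replicate 1 or 2 (adjusted p = 0.076, 0.053, 0.15 and 0.15). hscA (1.13) lost its call without deletion replicate 1 (0.060), and hscB (1.099) without wild-type replicate 3 or deletion replicate 1 or 2 (0.055, 0.053 and 0.092) and with median-ratio scaling (0.0505). Without an intensity trend, znuA and hscB were lost as well (0.13 and 0.079).

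Genes of central oxidative metabolism were higher in the deletion strain. Of 22 genes of the tricarboxylic acid and glyoxylate cycles, 20 rose and none fell, with the same counts adjusted over the list alone (set test adjusted p = 2.2e-08, and adjusted p = 0.17 with an estimated correlation). sucD rose from 201 ± 20.9 to 807 ± 73.8 TPM (log2 fold change 2.01, SE 0.11), followed by sucC (1.81, SE 0.08), sucB (1.69, SE 0.15) and the aconitase gene acnB (1.64, SE 0.10). Of 28 genes of aerobic respiration and ATP synthase, 22 rose and none fell, with 25 higher adjusted over the list alone (set test adjusted p = 9.2e-07, and adjusted p = 0.09 with an estimated correlation). The ATP synthase gene atpD rose from 170 ± 9.80 to 421 ± 4.15 TPM (1.31, SE 0.10), and the NADH dehydrogenase genes nuoL (1.57, SE 0.22) and nuoH (1.42, SE 0.18) rose too. With median-ratio scaling, 17 and 12 members of these lists were higher. Of 9 fatty acid oxidation genes, 8 rose, also adjusted over the list alone, and 7 with median-ratio scaling (set test adjusted p = 5.8e-05, and adjusted p = 0.17 with an estimated correlation). fadA (2.50, SE 0.12), fadB (2.16, SE 0.07), fadJ (1.85, SE 0.10) and fadE (1.64, SE 0.06) rose, the last from 1259 ± 54.8 to 3932 ± 169 TPM. sucC and sucD overlap, as do nuoL and nuoK, nuoH and nuoG, and fadI and fadJ. The call of nuoK (1.27) was lost without wild-type replicate 1 or 2 (adjusted p = 0.070 and 0.060) and with median-ratio scaling (0.088). It was also lost with quantile normalization (0.10), without an intensity trend (0.098) and in the voom fit (0.10). Without deletion replicate 1 the call of nuoK was lost too, at a log2 fold change of 0.90.

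Genes for uptake and use of carbon sources other than glucose rose in part. Of 70 tested, 27 rose and 1 (gatY) fell, against 34 higher and 2 lower adjusted over the list alone (set test adjusted p = 0.00018, and adjusted p = 0.15 with an estimated correlation). dctA, which encodes a C4-dicarboxylate transporter, rose from 651 ± 59.0 to 1509 ± 33.6 TPM (log2 fold change 1.21, SE 0.09). glpB (2.51, SE 0.49), glpC (2.34, SE 0.67) and srlA (1.48, SE 0.44) showed larger rises on fewer reads. glpB overlaps glpA and glpC, and srlA overlaps srlE. With median-ratio scaling, 17 were higher and 4 lower. The call of glpB was lost without deletion replicate 1 (adjusted p = 0.086). glpC was lost without wild-type replicate 1 or 3 or deletion replicate 1 or 2 (0.051, 0.076, 0.14 and 0.20) and srlA without the same libraries (0.090, 0.088, 0.19 and 0.19). gatY was lost without wild-type replicate 1 or 2 or deletion replicate 1 (0.056, 0.058 and 0.13). glpC and srlA were also lost with median-ratio scaling (0.069 and 0.092) and, with gatY, without an intensity trend (0.089, 0.059 and 0.25). Quantile normalization ended the calls of glpC and srlA too (0.060 and 0.10). A pseudocount of 0.1 ended that of glpC (0.068), and the replicate block and the voom fit that of srlA (0.10 and 0.092). gatY was positive with quantile normalization (log2 fold change 0.13, adjusted p = 0.12).

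Amino acid synthesis and uptake genes were higher in several lists. Of 19 branched-chain amino acid genes, 16 rose and none fell, with 17 higher adjusted over the list alone and 15 with median-ratio scaling (set test adjusted p = 4.8e-07, and adjusted p = 0.09 with an estimated correlation). ilvC rose from 32.4 ± 3.02 to 218 ± 14.05 TPM (2.72, SE 0.16), and the transporter genes livH (2.64, SE 0.43), livJ (2.15, SE 0.12) and livG (1.99, SE 0.34) rose with it. Of 14 methionine genes, 11 rose and metJ, the repressor of the pathway, fell by a small amount (log2 fold change -0.25). Adjusted over the list alone, 12 were higher and 1 lower, and with median-ratio scaling 9 and 1 (set test adjusted p = 4.0e-05, and adjusted p = 0.29 with an estimated correlation). metE (3.59), metQ (2.50), metI (1.77) and metL (1.61) showed the largest changes. metI overlaps metN, and livH and livG overlap livM. Of 24 genes for other amino acids, 17 rose and asnA and asnB, both asparagine synthetase genes, fell, against 18 higher and 2 lower adjusted over the list alone and 14 and 3 with median-ratio scaling (set test adjusted p = 0.00023, and adjusted p = 0.19 with an estimated correlation). gltB (2.77), gltD (2.76) and the glutamate dehydrogenase gene gdhA (2.55) rose. lysA (2.25) lost its call without deletion replicate 1 or 2 (adjusted p = 0.068 and 0.0503). The call of metJ was lost without wild-type replicate 2 or deletion replicate 1 or 2 (0.052, 0.062 and 0.11) and, like that of asnA (0.074), without an intensity trend (0.22).

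Of 8 histidine genes tested, 7 rose, against 8 adjusted over the list alone and 5 with median-ratio scaling (set test adjusted p = 0.0029, and adjusted p = 0.41 with an estimated correlation). hisA (log2 fold change 2.23, SE 0.32), hisC (2.18, SE 0.34) and hisB (2.04, SE 0.29) rose, and hisF (1.80, SE 0.36) lost its call without deletion replicate 1 (adjusted p = 0.078) and without an intensity trend (0.062). Of 21 tryptophan and aromatic amino acid genes, 10 rose and mtr, a tryptophan transporter gene, fell from 47.9 ± 9.15 to 15.1 ± 2.03 TPM (-1.59, SE 0.27), against 12 higher and 1 lower adjusted over the list alone and 7 and 1 with median-ratio scaling (set test adjusted p = 0.0084, and adjusted p = 0.17 with an estimated correlation). tyrB (1.83, SE 0.27), aroA (1.71, SE 0.29) and aroG (1.67, SE 0.14) rose. The call of aroA was lost without deletion replicate 1 (adjusted p = 0.060), and neighbouring his genes overlap.

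Ribosomal protein genes rose by small amounts. Of 54, 45 rose and rpmE fell, with the same counts adjusted over the list alone (median log2 fold change 0.50, set test adjusted p = 1.2e-06, and adjusted p = 0.10 with an estimated correlation). With median-ratio scaling, 17 were higher and 1 lower, and the list kept its direction. rplQ rose from 225 ± 20.6 to 544 ± 20.6 TPM (1.27, SE 0.10), and rpsQ (0.93, SE 0.12) and rpmC (0.92, SE 0.08), which overlap each other, rose as well. Of 12 translation factor genes, 6 rose and none fell, with 7 higher adjusted over the list alone and 3 with median-ratio scaling (set test adjusted p = 0.029, and adjusted p = 0.26 with an estimated correlation). tsf (0.70, SE 0.09), fusA (0.59, SE 0.07) and tufA (0.57, SE 0.06) rose, and tufA has a near-identical copy, tufB. Of 27 purine and pyrimidine genes, 5 rose and pyrG fell, with the same counts adjusted over the list alone and 2 higher and 2 lower with median-ratio scaling (set test adjusted p = 0.029, and adjusted p = 0.20 with an estimated correlation). purA rose from 209 ± 23.1 to 398 ± 22.1 TPM (0.93, SE 0.11). The translation factor list was lost without wild-type replicate 2 or 3 or deletion replicate 1 (adjusted p = 0.071, 0.052 and 0.10), with median-ratio scaling (0.13), with a mean of at least 10 TPM (0.059) and with the replicate number as a block (0.073). The purine and pyrimidine list was lost without wild-type replicate 3 or deletion replicate 1 (0.083 and 0.073), with a mean of at least 10 TPM (0.24), with the block (0.093) and in the voom fit (0.17). Calls were lost for rpmG (1.05) without wild-type replicate 1 or 3 or deletion replicate 1 or 2 (adjusted p = 0.090, 0.092, 0.14 and 0.11) and prfB (0.55) without deletion replicate 1 (0.12). carB (0.82) and pyrC (1.93) were lost without deletion replicate 1 (0.11 and 0.057) or 2 (0.11 and 0.16), and purN (2.31) without wild-type replicate 1 or 3 or deletion replicate 1 or 2 (0.070, 0.073, 0.062 and 0.26). pyrG was lost without wild-type replicate 1 or 2 or deletion replicate 1 or 2 (0.072, 0.051, 0.055 and 0.19). With median-ratio scaling, rpmG, prfB, carB and purN were lost as well (0.10, 0.16, 0.085 and 0.055), and without an intensity trend rpmG, prfB, purN, pyrG and rpmE (0.11, 0.074, 0.072, 0.13 and 0.068). Quantile normalization ended the calls of rpmG, prfB, carB and purN (0.098, 0.070, 0.092 and 0.057). The block ended those of rpmG and carB (0.063 and 0.060), and the voom fit that of rpmG (0.16).

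Type 1 fimbriae, AI-2 and indole signalling, and toxin-antitoxin lists also passed. Of 9 type 1 fimbriae genes, 7 rose and none fell, with 8 higher adjusted over the list alone and 6 with median-ratio scaling (set test adjusted p = 0.00032, and adjusted p = 0.15 with an estimated correlation). fimA, which encodes the major fimbrial subunit, rose from 387 ± 15.3 to 2104 ± 0.607 TPM (log2 fold change 2.44, SE 0.07), and fimC (2.71, SE 0.20) and fimI (2.32, SE 0.10) rose with it. Of 15 genes of AI-2 and indole signalling, 9 rose and the toxin-antitoxin genes mqsR and mqsA fell, with the same counts adjusted over the list alone and 7 higher and 2 lower with median-ratio scaling (set test adjusted p = 0.0495, and adjusted p = 0.29 with an estimated correlation). lsrR rose from 365 ± 25.9 to 1090 ± 25.4 TPM (1.58, SE 0.08), followed by lsrD (1.52, SE 0.25), lsrK (1.34, SE 0.10) and lsrB (1.099, SE 0.12). Of 22 toxin-antitoxin genes, 7 fell and none rose, against 9 lower and 2 higher adjusted over the list alone and 12 lower with median-ratio scaling (set test adjusted p = 0.00094, and adjusted p = 0.15 with an estimated correlation). chpS (-0.64, SE 0.06), mqsR (-0.56, SE 0.04) and dinJ (-0.35, SE 0.06) fell. chpS overlaps chpB, prlF overlaps yhaV and lsrD overlaps lsrC. The AI-2 and indole list was lost without wild-type replicate 1, 2 or 3 or deletion replicate 1 (adjusted p = 0.057, 0.083, 0.11 and 0.067), with median-ratio scaling (0.056), with a mean of at least 10 TPM (0.11), with the replicate number as a block (0.15) and in the voom fit (0.059). Calls were lost for fimG (2.21) without deletion replicate 1 or 2 (adjusted p = 0.087 and 0.098) and for prlF (-0.34) without deletion replicate 2 (0.072). mqsA was lost without wild-type replicate 1 or 2 or deletion replicate 1 or 2 (0.073, 0.071, 0.12 and 0.10). Without an intensity trend, fimG, prlF, dinJ and mqsA were lost as well (0.061, 0.14, 0.13 and 0.21).

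**Figure D3:**
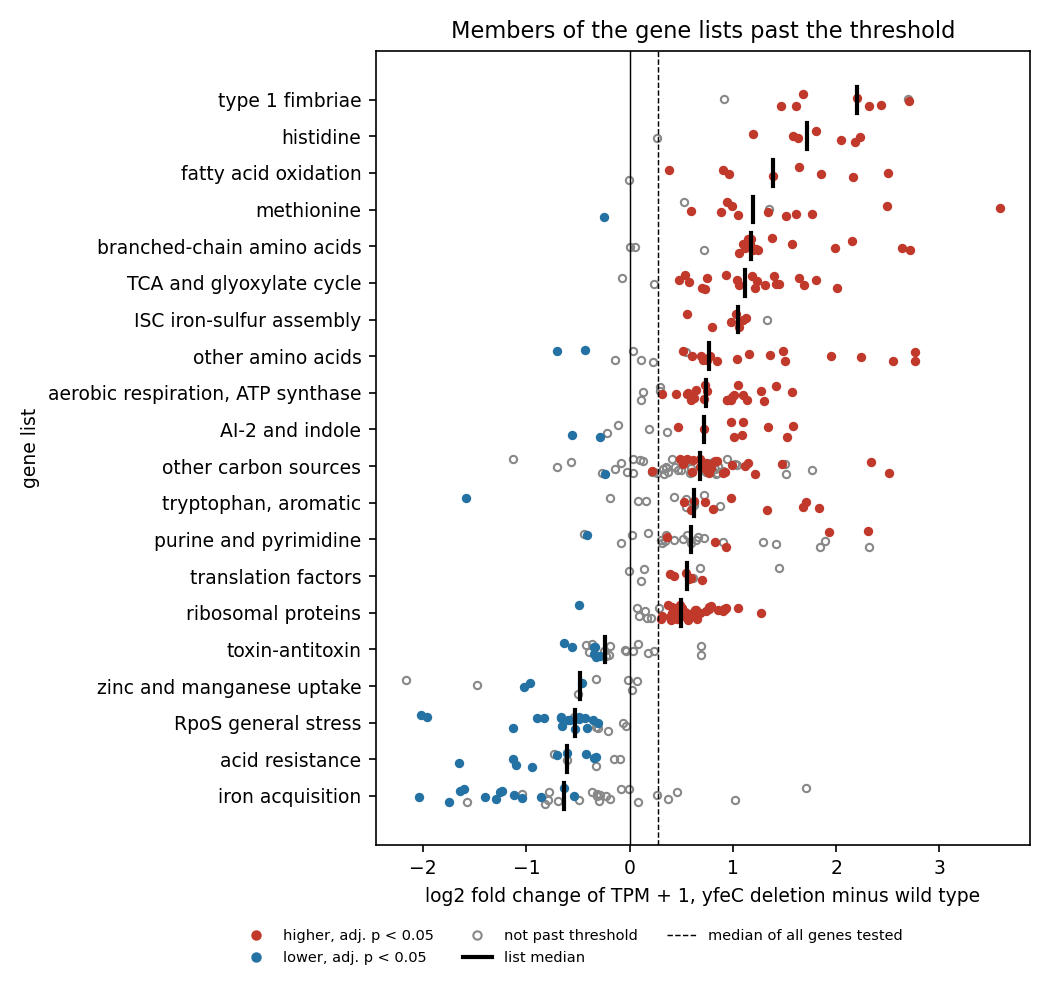
Log2 fold change of TPM + 1 (yfeC deletion minus wild type, horizontal axis) of each member of the 20 gene lists past the threshold, with filled points for genes past the threshold, open points for the others, a black bar at each list's median and a dashed line at the median of all genes tested, 0.27. All 5 lists called downward have medians below 0, and the 15 called upward have medians above the dashed line.

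The other 27 lists tested did not pass the set test, with adjusted p from 0.067 to 0.94. Of 18 heat shock genes, 10 rose and none fell, with 11 higher adjusted over the list alone but 3 higher and 3 lower with median-ratio scaling. ibpB, a small heat shock protein gene, rose from 1258 ± 101 to 4929 ± 57.7 TPM (log2 fold change 1.97, SE 0.07). The porin gene ompF rose from 860 ± 17.0 to 2780 ± 126 TPM (1.69, SE 0.06) and the protease gene ompT from 670 ± 58.5 to 2106 ± 121 TPM (1.65, SE 0.09). Of 17 outer membrane genes, 9 rose and 3 fell, with the same counts adjusted over the list alone and 5 and 3 with median-ratio scaling. Of 51 flagella and chemotaxis genes tested, 9 rose and none fell, with 3 higher adjusted over the list alone and 4 with median-ratio scaling. The set test of this list (adjusted p = 0.16) passed upward with median-ratio scaling (0.019), quantile normalization (0.038), the replicate number as a block (0.045) and fry (0.016). The heat shock list passed with quantile normalization (0.015) and fry (0.0023), and the outer membrane list under fry (0.0028). Among 10 growth arrest genes, 2 rose and 3 fell, with the same counts adjusted over the list alone and 2 and 5 with median-ratio scaling. raiA (0.53, SE 0.05) and uspA (0.59, SE 0.08) rose, and rmf (-1.01, SE 0.18) and dps (-0.42, SE 0.06) fell. Of 26 nitrogen limitation genes tested, 5 rose and 5 fell, with the same counts adjusted over the list alone and 3 and 6 with median-ratio scaling. astE (-1.68, SE 0.30), astA (-1.57, SE 0.30) and astB (-1.40, SE 0.26), genes of arginine breakdown whose neighbours overlap, fell. glnA, the glutamine synthetase gene, rose (2.14, SE 0.41) but lost its call without deletion replicate 1 (adjusted p = 0.060). Without an intensity trend, the calls of raiA, uspA, rmf, dps and astA were lost (adjusted p = 0.057, 0.064, 0.074, 0.085 and 0.054).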

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

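The voom fit on recovered reads, the thinned reads and the simulation by read number were chosen after the data were seen. The yfeC level stayed lower and past the threshold in every alternative run, with log2 fold changes from -10.89 (pseudocount 0.1) to -7.56 (pseudocount 5). The number of higher genes, 750 as reported, fell to 340 with median-ratio scaling, 393 with quantile normalization, 343 without an intensity trend and 247 with an absolute log2 fold change of at least 1, and ran from 352 to 648 with each library left out, where a lone deletion library is assumed to vary like the wild type. The number of lower genes, 304 as reported, was 478 with median-ratio scaling, 150 without a trend and 96 with the fold threshold, and ran from 208 to 267 with a library left out. The voom fit gave 619 higher and 455 lower genes, and thinning 704 and 300. Of the 20 lists, 0 passed with an estimated correlation, and 33 lists passed under fry, a test that does not compare a list with other genes. Left-out libraries gave 17 to 22 lists. gatY, called lower, was positive with quantile normalization (log2 fold change of gatY 0.13, adjusted p = 0.12). The glycolysis list went from downward and not past the threshold to upward and past it under fry (adjusted p = 0.037, against 0.34 to 0.99 in the others). Of the lists not past the threshold, 8, glycolysis included, had another direction under fry than under camera and up to 4 under each other alternative, and no list past the threshold changed direction. The median of the glycolysis list was 0.15, below that of all genes. Scaling and the fold threshold change the counts by construction, and the cause of the other shifts was not tested. With the replicate number as a block (replicate block), 589 genes were higher, 270 lower and 18 lists past the threshold. Wild-type replicate 3 has no same-numbered deletion library, so the block's fold changes are those without that library. Deviations of same-numbered libraries did not correlate (r = -0.003 and -0.025). With 2 deletion libraries, whose deviations mirror each other, this cannot exclude a shared day or culture, which the labels leave unstated. Of 200 other named genes called, 62 lost the call without a trend, 31 with median-ratio scaling, 30 with quantile normalization and 18 with the block. So did 14 of 199 tested in the voom fit and 6 of 198 after thinning. Without wild-type replicate 1, 2 or 3, 20, 17 and 16 of the 200 were lost. Leaving out either deletion library ended more of these calls than any other setting but the fit without a trend. Such a fit rests on 1 deletion library. Only gatY changed direction in any alternative. Rescaling after removal of stable RNA genes was not run, because none are among the genes analysed here. The median was 29 to 40 reads per gene. In simulated libraries with changes of 1 log2 unit and a dispersion of 0.005, the fit recovered 3% of genes with 2 to 10 wild-type reads, 38% of those with 10 to 50 and 94% of those with more, and at 10 times the depth 85%, 100% and 100%. At a dispersion of 0.03 these shares were 2%, 5% and 19%, and 57%, 80% and 81%. Under these settings depth limited the calls of genes with few reads.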

Other observations

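The genes in this paragraph and the next were chosen after their values were seen, apart from raiA and the ast genes. Several neighbouring genes moved together. The 5 dipeptide transporter genes dppA, dppB, dppC, dppD and dppF rose by log2 fold changes of 1.19 to 2.19, and the 5 glycogen genes glgB, glgX, glgC, glgA and glgP by 0.56 to 1.05. The phage shock genes pspA to pspE rose by 0.67 to 1.69. Calls were lost for pspB, the largest of these, without deletion replicate 2 (log2 fold change 1.32, limma adjusted p = 0.083), for pspC without wild-type replicate 3 or deletion replicate 1 (0.060 and 0.12), for dppD without deletion replicate 1 or 2 (0.060 and 0.065), for glgB without the same libraries (0.070 and 0.096) and for astD without deletion replicate 1 (0.075). With median-ratio scaling, glgB, glgX and pspC were lost (0.083, 0.058 and 0.061), and without an intensity trend dppD, glgB, glgX, pspB, pspC, pspE and astA (0.053, 0.059, 0.057, 0.078, 0.087, 0.052 and 0.054). Quantile normalization ended the calls of glgB and pspC (0.080 and 0.060), and the replicate block that of glgB (0.051). The 5 arginine breakdown genes astC, astA, astD, astB and astE fell, with log2 fold changes of -1.68 to -0.95. Runs of 13 neighbouring ribosomal protein and associated genes rose at both rplQ to rpsH and rplX to rpsJ. Their median log2 fold changes were 0.61 and 0.64, against 0.27 for all genes tested. With median-ratio scaling, 17 of the 54 ribosomal protein genes were called higher.

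The most abundant transcripts went both ways. ychH fell from 29742 ± 1458 (SD, n = 3) to 14681 ± 729 TPM (SD, n = 2), with a log2 fold change of -1.02 (SE 0.06, limma adjusted p = 1.6e-05), and bssR from 25600 ± 350 to 14461 ± 589 TPM (-0.82, SE 0.04). raiA, which encodes a ribosome-associated inhibitor, rose from 24474 ± 1140 to 35236 ± 139 TPM (0.53, SE 0.05), and yobF from 15640 ± 321 to 21915 ± 1015 TPM (0.49, SE 0.05). zraP, which encodes a zinc-binding periplasmic protein, fell from 5984 ± 304 to 1634 ± 57.3 TPM (-1.87, SE 0.06). rpoS itself was higher in the deletion strain (0.42, SE 0.05, adjusted p = 0.0008), while the genes of the RpoS list were lower. With median-ratio scaling the rpoS value was 0.15 (adjusted p = 0.089), and without an intensity trend the calls of rpoS, raiA and yobF were lost (0.082, 0.057 and 0.064). With quantile normalization the bssR value was -0.21 (adjusted p = 0.13).

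Of the tests below, the removal of the 100 most abundant genes, the growth and stress index, the splits of the libraries, the sum of hyc genes without hycI and the sum with a TPM-based depth factor were chosen only after the result was seen. More genes were called higher than lower, with a median log2 fold change of 0.27. Library depth was argued against as the cause, since the median was 0.262 after thinning every library to the lowest total. A smaller share of TPM in the most abundant genes is a candidate explanation: the 100 most abundant took 52.8% to 53.0% in the wild type and 46.9% to 47.0% in the deletion strain, and without them the median was 0.113. That value lies between the bounds set for and against this explanation (0.1 and 0.2). Removal and rescaling move the other genes by nearly the same amount, which the shares of the 100 genes fix, so the value is no separate test. A broad rise of transcripts in the deletion strain cannot be told apart from this explanation, because TPM are relative. In the voom fit, on recovered reads relative to each library's total, the median was 0.097. The size of the shift thus depends on the unit.

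An index of mean log2 levels of ribosomal protein, tricarboxylic acid cycle and respiration genes minus those of the RpoS list was -1.09, -1.02 and -1.06 in the wild-type libraries and 0.28 and 0.28 in the deletion libraries. The difference of 1.34 was 20.1 times the range among the wild-type libraries. The lists were taken into the index after their directions were known, and the labels do not say that the replicates are separate cultures, so the wild-type range may be technical. A different growth phase or density of the deletion cultures at harvest therefore cannot be told apart from an effect of yfeC, and both stay open.

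Few reads lay behind the rise of hycA, hycD and hycF, and chance at such numbers is a possible explanation. The other 6 hyc genes together had 187, 190 and 201 reads per 1000000 in the wild type and 329 and 374 in the deletion strain, a ratio of 1.82 (95% counting interval 1.61 to 2.06). That lies between the bounds set beforehand for and against chance (1.5 and 2). With the TPM-based depth factor used for genes with few reads, the ratio of the same 432 and 601 reads was 2.07 (1.83 to 2.35), past the upper bound but not by more than its interval. Both intervals lie above 1.5, so counting error alone would not bring the sum of these 6 genes down to that bound. The intervals were added after the ratio was seen and leave out the spread between libraries. The bound set beforehand against chance was 2, so no verdict was drawn from them. The upper bound was not clearly passed, and its side depended on the depth factor. The sum does not settle chance in hycA, hycD and hycF themselves, which were named for their large rise. hycI held most of these reads, and without it the ratio was 2.43, a sum chosen after the first ratio was seen and not used to decide. No biological explanation was tested.

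The 5 libraries can be split into groups of 3 and 2 in 10 ways, too few for a share under 0.05. The real split gave 1054 genes past the threshold, the only 1 of the 10 to give as many, and the highest of the others gave 0. Every other split puts both genotypes in at least 1 group, so the genotype difference adds to the spread within groups. Few calls could be foreseen there, and no conclusion was drawn from the contrast.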
